A study of Drosophila melanogaster with 2 samples.

How the data were processed

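Binding of a Gsc-eGFP fusion protein was mapped by chromatin immunoprecipitation with an anti-GFP antibody and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos 0 to 24 h old. The labels give 1 group of 2 biological replicates, with chromatin broken by sonication to fragments of 200 to 800 bp. There is no second condition, and a control library was not analysed here.

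Per the labels, coordinates are on the dm6 build. The peak caller, the aligner and their versions are not given in the sources used here. The authors deposited, for each replicate and for both replicates together, a list of all regions ranked by the irreproducible discovery rate (IDR) and a thresholded list taken from it. In every deposited list the score is the authors' scaled IDR value per region, and the weakest thresholded region of the main list had a −log10 IDR of 2.00, that is an IDR of 0.01. The signal value of each region is the authors' own, on a scale the sources used here do not give, and it was used to describe and rank regions within a list. The −log10 IDR value that the authors deposited in the ranked lists was used only to check the threshold, and the deposited −log10 q-values were not used. The files hold no read counts, so the depth of the libraries is unknown. Intervals on shares of regions are 95% Wilson intervals and cover counting error over regions only.

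The main list was the thresholded list made from both replicates that is not the conservative one. The ranking behind it compares 2 sets of regions that match neither replicate's own list, so its IDR is not shown to be one between the replicates. The ranking behind the conservative list compares the replicates' own lists. The regions of the main list were checked against the ranked lists, and all 1655 were found in 1 of them. In that ranked list 301 further regions had a score at or above the threshold but were absent from the thresholded list, 171 of them on contigs outside the arms. These regions were kept out of the background, a condition added once they had been found in the files and not part of the earlier plan. The ranked lists of both replicates together also hold 16 unnamed columns that could not be tied to a replicate by name, and these were left out. Values per replicate came from each replicate's own ranked list, through the region with the longest overlap.

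Genes, transcripts and exons were taken from Ensembl release 115, and sequence from the Release 6 reference genome, whose arms carry the names and lengths used in that annotation. Regions on sequences outside the 7 arms 2L, 2R, 3L, 3R, 4, X and Y were given no gene and no sequence. This left 1470 regions of the main list. The background was 115913 candidate regions: those of the ranked list on the same arms, below the threshold score and over no region of the main list.

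The following tests and gene lists were fixed before the data were examined. Overlap between replicates was tested against 1000 random draws from the ranked list of replicate 2, with as many regions per chromosome and at least 1 bp of overlap (one-sided). Each summit was placed in a promoter (within 500 bp of the transcription start site, TSS, of a protein-coding gene), 5' UTR, CDS, 3' UTR, intron or intergenic sequence, in this order, and shares were compared with the candidates by two-sided Fisher's exact tests with Benjamini-Hochberg (BH) adjustment. Arms and noncoding genes (within 200 bp of a tRNA, snRNA, snoRNA or rRNA gene, or inside the histone cluster) were tested alike. For 9 sequence words and for all 2080 6-mers, the share of regions with the word within 50 bp of the summit on either strand was compared with up to 5 candidates per region, drawn in 10 bins of GC content. The signal of regions with and without TAATCC was compared by a two-sided permutation test with 100000 resamples. For 18 gene lists, the number of genes nearest to at least 1 region was compared with 100000 random gene lists matched on the number of candidate regions per gene (one-sided permutation test, BH over lists). A two-sided p was computed as well for every list and adjusted over the 18 lists. Of the listed symbols, 1 did not match a gene of the annotation and was not used. Only genes nearest to at least 1 candidate or main-list region were tested, 9245 of 13968 protein-coding genes. A gene without candidates was thus tested only if it was occupied. This left 34 of 82 ribosomal protein genes, and 10 of 17 listed for abundantly transcribed genes and for Notch targets. Counts of occupied genes refer to the tested genes and not to whole classes. All adjusted p-values are BH values and the threshold was 0.05. Regions and genes in one genome are not replicates, so these p-values describe these lists and not the spread between embryos.

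The text names genes by a rule fixed at the same time. It takes Gsc with every region assigned to it, the genes nearest to the 12 strongest regions and the 6 genes with most regions. It also takes up to 4 members per list with the strongest regions, up to 5 6-mers per direction with the lowest adjusted p under 0.05, and the 3 regions per direction that differ most between replicates. The region of 1 gene that this rule would name is not reported here.

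The tests were run on simulated data with known answers. Of 300 location tests on random lists of 1470 candidates, 1 passed, and of 350 tests by arm, 2 passed. A random 6-mer planted in 5% of 1470 windows was recovered in 5 of 5 runs, and in 2% of windows in 1 of 5 runs. For lists of 15 genes from the 9245 tested, 1 of 200 random lists reached an unadjusted p under 0.05, against 114 of 200 lists in which occupied genes were 4 times as likely to be drawn. With replicate 2 redrawn at random, 2 of 50 overlap tests on 967 regions passed, and 50 of 50 did once 10% of the regions were placed at replicate 1 sites.

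Most alternatives were fixed with the tests, and those added after the data were seen are named as such. Alternatives covered the conservative list, each replicate's own list, the stronger 50% of the main list, other window sizes, other backgrounds, other rules for assigning genes, and leaving out the Y chromosome. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.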

Results

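The data describe where a GFP-tagged Gsc protein was found on the genome of whole fly embryos. Gsc is the Drosophila homologue of Goosecoid, a homeodomain transcription factor. Embryos of 0 to 24 h were used, in 2 biological replicates. The main list from both replicates held 1655 regions, the conservative list 1575, the list of replicate 1 1188 and that of replicate 2 967. In the main list the signal value had a median of 97.3 and ran from 2.03 to 1323, and 80.7% of regions had the same width of 336 bp. The main list covered 506 kb. The ranked list it was taken from held 121914 regions.

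On the arms, the strongest regions mostly lay close to start sites, led by that of Ugalt. A region on an X contig, with a signal of 1266, would come between CG14100 and Adf1 and was given no gene. The region with the highest signal lay 24 bp from the TSS of Ugalt, a UDP-galactose transporter (X, 2703733 to 2704042), with a signal of 1323 in the main list and 663 ± 24.0 (SD, n = 2) in the replicates' own lists. The next was 94 bp from the TSS of CG14100 (3L, 19590473 to 19590762), at 649 ± 28.2 (SD, n = 2). Adf1, a Myb-type transcription factor, had a region in an intron, 782 bp from its nearest TSS (2R, 6662909 to 6663210, 584 ± 27.2). The region of ph-p, a Polycomb group gene, was also intronic, 503 bp from the nearest TSS (X, 2137203 to 2137506, 554 ± 68.2). Promoter regions followed at CG7601 (3R, 29736701 to 29736987, 496 ± 10.8) and at Tcs5 (3L, 5139350 to 5139640, 482 ± 62.6). Chro, which codes for the chromodomain protein Chromator, had its region 87 bp from the TSS (3L, 22878746 to 22879041, 468 ± 15.5). The 5 others of the 12 strongest on the arms lay at CenG1A (2L, 13835321 to 13835605, 422 ± 41.1), the wing vein gene px (2R, 22514168 to 22514434, 416 ± 1.06), the adaptor protein gene Shc (3L, 9426741 to 9427023, 409 ± 39.5), an intron of CG11050 (2L, 6612584 to 6612866, 399 ± 48.9) and mRpS10, a mitochondrial ribosomal protein gene (3R, 15229394 to 15229661, 403 ± 39.5). Of these 12, 9 were promoter regions, and the median distance to the nearest TSS was 105 bp. All 12 were found again in the conservative list and in each replicate's own list.

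No region of the main list was assigned to Gsc itself (2L, 583540 to 594685). The ranked list held 23 candidate regions nearest to its TSS, the strongest with a signal of 69.0, which was above that of 99.9% of all candidates. The closest region of the main list had its summit 5138 bp from the gene, in the CDS of Pph13, another paired-like homeobox gene, with a signal of 60.2.

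Myo81F and DIP-lambda, at the centromeric ends of their arms, had most regions. Myo81F, a myosin gene on 3R (567076 to 2532932), had 12 regions assigned, with a median signal of 74.3 and summits from 42140 to 1870528, in part outside the gene. DIP-lambda on 2R (326768 to 705848) had 9, with a median of 63.9 and summits from 33925 to 399410, also in part outside the gene. The weakest regions of these 2 genes, at 15.1 and 11.3, were overlapped by stronger regions, as were all 48 regions with a signal under 30. DIP1 on X had 8, with a median of 97.8, whose summits lay from 21713628 to 21769969, outside the gene. ARY on the Y chromosome (702430 to 704048) had 7, with a median of 129, whose summits lay from 787755 to 989410, outside the gene. Hr4, a nuclear receptor gene on X (1941940 to 2007956), had 7 regions, all inside the gene, between 74.0 and 260.3. Ids on 3L (3378268 to 3380083) had 7, which lay between 3382608 and 3396247, beside the gene. In all, 1126 protein-coding genes were nearest to at least 1 region, and 222 of them to several.

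The replicates placed their regions at the same sites far more often than random draws did. Of the 967 regions of replicate 2, 729 overlapped a region of replicate 1 (75.4%, 95% interval 72.6 to 78.0), against 6.22% in draws from the ranked list and 15.9% in draws from its top 10%. In the other direction, 727 of the 1188 regions of replicate 1 overlapped a region of replicate 2 (61.2%, 58.4 to 63.9). No draw of 1000 from the full ranked list exceeded 76 regions (one-sided permutation test, p = 0.001, the smallest that 1000 draws can give). Of the regions of the main list, 721 were in both replicates' thresholded lists and 436 in neither.

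Regions strong in replicate 1 were mostly strong in replicate 2 as well. Over the 1589 regions of the main list with a value in both, Spearman's rho was 0.711 and Pearson's r of log2 signal was 0.755, across regions, which are not independent replicates. The median log2 ratio of replicate 2 to replicate 1 was -0.22, with an SD over regions of 0.66. In 163 regions the replicates differed more than 2-fold, and 66 regions had no value in at least 1 replicate. Over 7243 candidate regions spaced evenly through the list, rho was 0.19. The regions highest in replicate 1 relative to replicate 2 lay near cue (log2 ratio -4.25), DIP-lambda (-3.85) and CG43815 (-3.32). Those highest in replicate 2 lay near CG44438 (3.38), CG42710 (3.10) and SerT, the serotonin transporter gene (3.01). Of these 6 regions, 5 were overlapped by a stronger region of the main list.

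**Figure D1:**
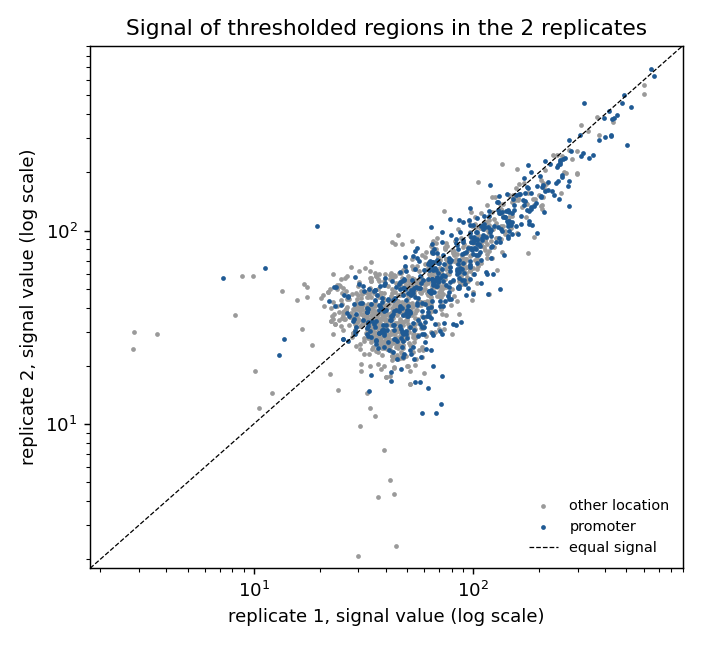
Signal value of each main-list region in replicate 1 (horizontal) and replicate 2 (vertical), both on log scales, with 1 point per region on a chromosome arm; promoter regions are blue and the dashed line marks equal signal. The strongest regions lie close to the line, and a few weak regions lie far from it in both directions.

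Promoters held 532 of the 1470 regions (36.2%, 95% interval 33.8 to 38.7), against 8.40% of candidates. The odds ratio was 6.19 (5.55 to 6.90), and Fisher's exact test gave an adjusted p of 8.54e-188. Coding sequence was far less common, with 50 regions (3.40%) against 22079 of 115913 candidates (odds ratio 0.150, adjusted exact p = 4.00e-72). The log2 odds ratio of coding sequence was -2.74 here, -5.04 without replicate 1 (6 regions), -4.64 without replicate 2 (10) and -7.43 in the stronger 50% of regions (1). Candidates were not matched on GC in these tests, and GC within 50 bp was 36.2% in the list and 47.8% in all candidates. Against uniform random positions the log2 odds ratio was -2.15 for coding sequence and 2.20 for promoters, the latter against 2.63 here. The 3' UTR, with 8 regions against 1.67% of candidates (adjusted exact p = 0.000282), and intergenic sequence, with 361 regions or 24.6% against 32.2% (adjusted p = 3.87e-10), were also under-represented. Introns held 511 regions, or 34.8% against 37.9% (odds ratio 0.872, adjusted exact p = 0.0154). This difference no longer passed in the conservative list (adjusted exact p = 0.0665). The 3' UTR call was lost against the top 10% of candidates (adjusted exact p = 0.214). The intron share turned to a log2 odds ratio of 0.09 with a promoter window of 200 bp and to 0.06 against the top 10% of candidates. The 5' UTR held 8 regions, or 0.544% against 0.755% (adjusted exact p = 0.446). Promoter regions had a median signal of 126 (quartiles 83.6 and 211), intron regions 92.5 (71.5 and 147.7) and intergenic regions 89.3 (69.0 and 126.8). In 4 equal bins of rising signal, promoters took 21.5%, 31.3%, 36.8% and 55.2% of regions.

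**Figure D2:**
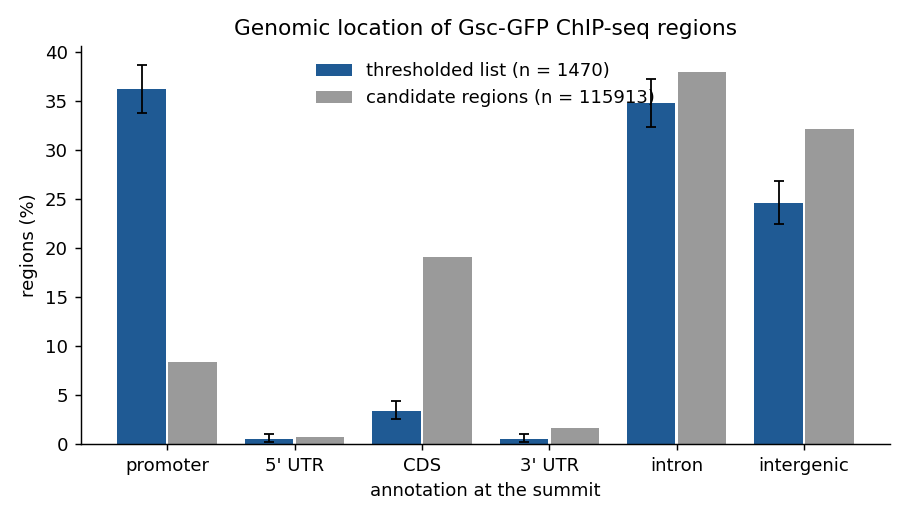
Share of summits (vertical, percent) in each annotation class (horizontal) for the 1470 regions of the main list, in blue with 95% Wilson intervals, and for the 115913 candidate regions, in grey. Promoters hold 36.2% of regions against 8.40% of candidates, and coding sequence 50 regions, or 3.40%.

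Regions were spread over the arms much as the candidates were, with 2 exceptions. The X chromosome held 298 regions, 20.3% against 17.4% of candidates (odds ratio 1.21, 1.06 to 1.37, adjusted exact p = 0.0159). This count leaves out 185 regions on contigs assigned to X but not placed on it. Arm 3R held 312, 21.2% against 27.1% (odds ratio 0.726, 0.640 to 0.823, adjusted exact p = 2.12e-06). Arm 2L, with 280 regions against 16.8% of candidates, had an adjusted exact p of 0.0633, which was 0.0305 in the conservative list and 0.0334 without replicate 1. Arms 2R and 3L and the Y chromosome, which held 10 regions, had adjusted p-values of 1, 0.335 and 0.335. Chromosome 4 held no region of the main list and 36 candidates (adjusted exact p = 1), and 4 ranked regions there reached the threshold score but were absent from the main list.

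The core word of homeodomain proteins with lysine at position 50, TAATCC, was not detectably more common at the summits than in matched sequence. It lay within 50 bp of 54 of 1470 summits (3.67%, 95% interval 2.83 to 4.76), against 3.41% of GC-matched candidates. Fisher's exact test gave an odds ratio of 1.08 (0.801 to 1.46) and an adjusted p of 0.751. None of the 9 fixed words passed, and 2 had an unadjusted p under 0.05. These were TAATTA, the core word of most other homeodomains, at 7.89% against 9.87% (adjusted exact p = 0.147), and TTTATG, of the Hox and Caudal type, at 11.8% against 13.9% (adjusted p = 0.147). The call for TAATTA changed with the regions and the background. Its log2 odds ratio was -0.79 without promoter regions (adjusted exact p = 0.00187), -0.44 with 1 region kept where regions overlapped (0.0292) and 0.77 against flanks of the same regions (0.000241). The GAGA factor word GAGAG was at 8.57% against 8.83%, and its log2 odds ratio was -0.91 against the flanks (adjusted exact p = 7.55e-09). The flanks were not matched on GC, which was 36.2% within 50 bp of the summit and 45.0% at 300 to 400 bp, a difference in the direction of both flank results. The Zelda word CAGGTA was at 1.97% against 1.70%, the DREF word TATCGATA at 0.340% against 0.250%, and the E box CATATG at 3.54% against 3.27%. The strict paired-type dimer TAATCNGATTA was in no region and 2 of 7194 matched candidates, and the wider form TAATYNRATTA in 2 regions and 35 candidates (adjusted exact p = 0.227).

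TAATCC also had no detectable relation to the strength of a region. The median log2 signal was 6.61 in the 54 regions with the word and 6.61 in the 1416 without it (difference 0.0015, two-sided permutation test, p = 0.992). From the weakest to the strongest of 4 equal signal bins, the word was in 14, 13, 11 and 16 regions.

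Among all 6-mers, 38 were more common and 20 less common at the summits than in GC-matched candidates, and the differences were small. The lowest adjusted p-values were those of TAAGCA (9.66% of regions against 6.10%, adjusted exact p = 0.00354), ACAGTG (6.12% against 3.48%, 0.00354), TCTTAA (11.5% against 7.78%, 0.00354), ACTGTA (5.99% against 3.42%, 0.00404) and AAGCTA (7.69% against 4.75%, 0.00404). Words lower at the summits were CAAAAA (18.2% against 23.5%, 0.00354), CAAACG (2.24% against 4.27%, 0.0231), TGAAAA (14.4% against 18.4%, 0.0231), ATTTTC (14.9% against 18.9%, 0.0231) and CACACA (5.03% against 7.69%, 0.0231). The highest odds ratio of a passing word was 2.43. With windows of 100 bp on either side, 149 words were more common, led by ACAGTG at 22.2% of regions against 8.45% (odds ratio 3.10, 2.67 to 3.59, adjusted exact p = 7.72e-43). The counts fell to 8 higher and 4 lower words without replicate 1, and to 6 and 1 in the stronger 50% of regions. Each of the 10 words named lost its call under at least 1 alternative, in part with fewer regions and a log2 odds ratio as large, as for AAGCTA in the stronger 50% (0.76 against 0.74) and CACACA without replicate 1 (-0.86 against -0.65). ACAGTG at the summit lost it against candidates matched on promoters as well (adjusted exact p = 0.144) and in the stronger 50% (0.563).

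Of the 18 gene lists, 3 had more occupied genes than matched random lists. Among genes chosen for abundant transcription, as a control for unspecific signal, 5 of 10 tested were occupied against 0.808 expected (adjusted permutation p = 0.0122). They included the chaperone gene Hsp83 (signal 213), the actin gene Act5C (207), the enolase gene Eno (184) and the ATP synthase gene blw (183). Of the Notch targets, 4 of 10 were occupied against 0.802 expected (adjusted permutation p = 0.0410). All 4 belong to the Enhancer of split complex on 3R, so they are neighbours: E(spl)m3-HLH (154), E(spl)malpha-BFM (136), E(spl)m7-HLH (99.9) and E(spl)mdelta-HLH (71.5). Of the segment polarity genes, 7 of 14 were occupied against 2.62 expected (adjusted permutation p = 0.0410), among them the Hedgehog receptor gene ptc (167), the T-box gene mid (160), the Wnt ligand gene wg (90.0) and nkd (76.4). These 4 regions lay between 5298 and 20414 bp from the nearest TSS, and none was in a promoter. With two-sided p-values the segment polarity and Notch lists no longer passed (adjusted permutation p = 0.0821 each), and the abundantly transcribed list did (0.0245). The segment polarity call was lost in the conservative list (adjusted permutation p = 0.220), without replicate 1 (0.383), without replicate 2 (0.388), in the stronger 50% of regions (0.609), with summits within 2 kb of a TSS of the gene (1), with gene bodies and 5 kb upstream (0.965) and without promoter regions (0.0504). The segment polarity call held without matching (adjusted exact p = 0.0111). The Notch call was lost without replicate 1 (0.350), in the stronger 50% (0.112), within 2 kb of a TSS (0.571), without matching (exact test, 0.113) and without promoter regions (0.196). It held in the conservative list (adjusted permutation p = 0.0455) and without replicate 2 (0.0359). With gene bodies and 5 kb upstream it held with 9 of 12 genes (0.00036), though 1 region can then count for several genes. The abundant transcription call was lost only when promoter regions were left out (0.196). Some of these folds stayed about as large: without promoter regions they were 6.58 for Notch targets, 5.77 for abundantly transcribed genes and 3.17 for segment polarity genes, against 4.99, 6.19 and 2.68 with all regions. In the stronger 50% of regions the fold of the Notch targets was 5.78.

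The other 15 lists did not pass. Head patterning genes had 3 of 15 occupied against 2.68 expected (adjusted permutation p = 0.720): slp2 (274), ems (119) and oc (100.4). Their fold of 1.12 ranged from 0 with summits within 2 kb of a TSS to 2.70 without replicate 1, and passed in no alternative. Pair-rule genes had 3 of 11 (1.82 expected, 0.688), slp2, sob (109) and odd (93.1). None of 9 trunk gap genes was occupied, against 1.48 expected (adjusted permutation p = 1). Hox and Hox-like genes had 3 of 12 (2.14 expected, 0.688), Antp (76.9), bcd (75.6) and zen (66.2). Dorsoventral genes had 6 of 16 (2.93 expected, 0.243), led by brk (155), dpp (104), sog (102) and Dr (100.3). Foregut and stomatogastric genes had 3 of 14 (2.20 expected, 0.688), slp2, bowl (274) and wg. Neural precursor genes had 2 of 14 (1.98 expected, 0.782), insc (101) and pros (61.2). The K50 and paired-like homeobox genes had 5 of 19 (3.19 expected, 0.597), among them oc, CG9876 (88.6) and bcd. Neuroendocrine genes had 2 of 16 (1.44 expected, 0.699), amon (332) and Pal2 (45.5).

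Lists of other tissues and the remaining control lists did not pass either. Muscle genes had 3 of 9 occupied (1.16 expected, adjusted permutation p = 0.347), sls (161), bin (134) and Mef2 (69.4). Glial genes had 1 of 7 (0.612 expected, 0.713), moody (304), and blood and fat body genes 2 of 8 (1.23 expected, 0.688), crq (194) and ush (150). Ribosomal protein genes had 4 of 34 (4.47 expected, 0.782), RpS27 (200.4), RpL34b (178), RpL23A (143) and RpL5 (69.3). Odorant receptor genes had 2 of 51 (6.43 expected), Or56a (65.8) and Or43a (57.1), with a two-sided adjusted p of 0.299. Yolk, vitelline and chorion genes had 1 of 11, 0.995 times the expected number (0.782), Vm26Aa (64.5).

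**Figure D3:**
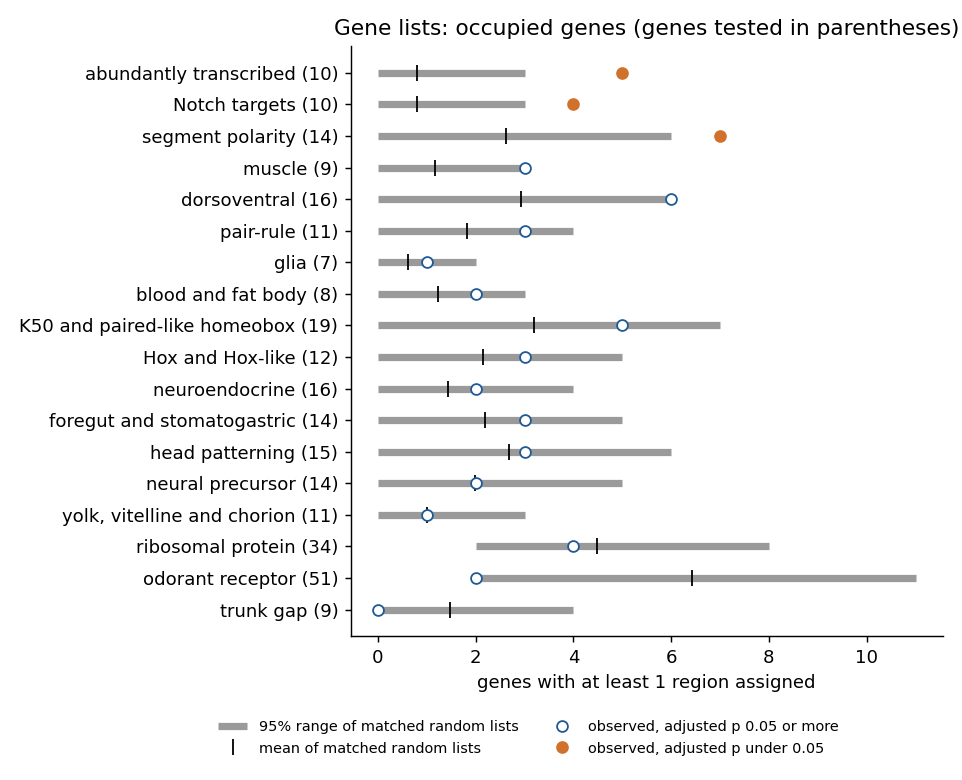
Number of genes with at least 1 assigned region (horizontal) for each gene list (vertical, genes tested in parentheses); circles are the observed numbers, filled orange where the adjusted p is under 0.05, ticks are the means and grey bars the 95% ranges of matched random lists. Abundantly transcribed genes (5 of 10), Notch targets (4 of 10) and segment polarity genes (7 of 14) lie above their ranges.

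Few regions lay near tRNA, snRNA, snoRNA or rRNA genes or in the histone cluster, and other noncoding genes were not tested. Of 1470 summits, 1 lay within 200 bp of a tRNA gene, and none near an snRNA, snoRNA or rRNA gene or in the histone cluster (2L, 21416953 to 21541681). None of the 5 classes passed Fisher's exact test, and none had an unadjusted p under 0.05. Few candidates lay there as well, from 4 in the histone cluster to 31 at snoRNA genes, so a difference was not detectable with these numbers.

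**Figure D4:**
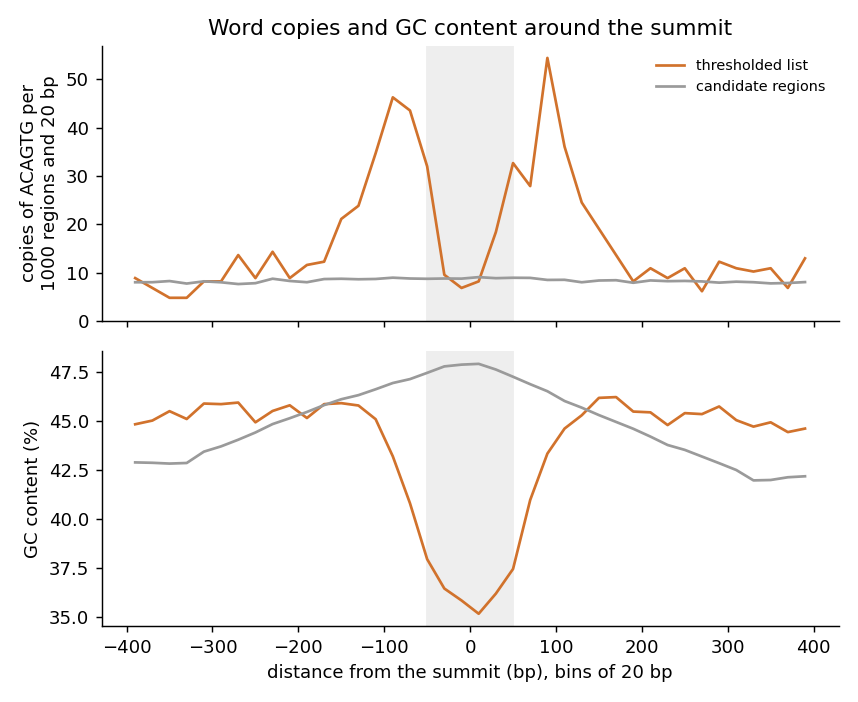
Copies of ACAGTG per 1000 regions and 20 bp (upper panel) and GC content in percent (lower panel) against the distance from the summit in bp, for regions of the main list (orange) and candidate regions (grey); the shaded band marks the 50 bp on either side used for the word tests. Copies rise to 54.4 at 80 to 99 bp and are 8.16 at 0 to 19 bp, where the GC content is 35.2%.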

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

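The regions on unplaced contigs and those absent from the thresholded list were set beside the others only after the data were seen. No weighing of causes was made for either, and no biological explanation was tested.

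Part of the main list lay on sequence that the comparisons of location, words and genes did not use. Of the main list, 185 regions (11.2%) lay on 121 contigs that are assigned to X but not placed on it. Their median signal was 94.8 (quartiles 74.1 and 157), against 97.4 (72.1 and 159) on the arms, and the strongest reached 1266. Contigs of all kinds together held 3.32% of the ranked regions below the threshold score, so this share is not one of X contigs alone. Of all 121914 ranked regions, those that passed included, 1063 lay on X contigs and 2675 on contigs without a chromosome. No region of the main list lay on a contig without a chromosome.

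A further 301 regions had a score at or above the threshold but were not in the thresholded list. Their median signal was 100.3 and the strongest reached 3549, above every region of the main list. Of these, 130 lay on the arms and 126 on contigs without a chromosome.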

How the results depend on the processing

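No paired analysis was possible because the design has 1 group. The alternatives that drop overlapping regions or widen the word window with promoter matching were chosen after the data were seen. Of 74 alternative values for the main results, 51 were classed as unchanged, 19 as moved and 4 as reversed. Unchanged allowed for shifts in counts and correlations, such as 30 higher 6-mers in the conservative list against 38. Of 453 values for single classes, words and lists, 376 were classed as unchanged, 50 lost their call, 5 gained it and 22 changed sign. A change of direction was not scored for gene lists and noncoding classes. Their values counted as unchanged whenever the call stayed the same. Head patterning counted so at folds of 0 within 2 kb of a TSS and 2.70 without replicate 1, against 1.12 in the main setting. Where a main result moved or reversed, the cause was not tested. The depth is unknown, so its effect could not be assessed.

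Leaving out replicates gave 967 to 1188 regions, 8 to 32 higher and 4 to 13 lower 6-mers, and 1 to 2 gene lists above chance. Spearman's rho between replicates was 0.758 on the conservative list and 0.814 on regions thresholded in both. Counts of higher and lower 6-mers were 6 and 1 in the stronger 50% of regions, 149 and 103 with 100 bp windows, 65 and 36 with promoter matching, and 179 and 151 with both; lower words were 13 in the conservative list. Gene lists above chance were 1 in the stronger 50%, 1 with summits within 2 kb of a TSS and 0 without promoter regions.

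The promoter log2 odds ratio stayed between 2.15 and 3.22. TAATCC turned to a log2 odds ratio of -0.12 with 100 bp windows, -0.161 with these and promoter matching and -0.157 without promoter regions. It rose from 0.113 in the main setting to 0.362 in the conservative list, 0.338 without replicate 1 and 0.338 without replicate 2. In the conservative list its signal difference turned to -0.0450. Neither the word nor its signal difference passed in any setting. With a 200 bp promoter window the 5' UTR turned to 0.0783 and introns to 0.0861, and introns to 0.0583 against the top 10% of candidates. Without a replicate, arm 3L ran from -0.0327 to 0.204, CAGGTA from -0.0278 to 0.178, GAGAG from 0.0446 to 0.0939 and TATCGATA from -1.27 to 0.466. CAGGTA turned to -0.54 in the stronger 50%, -0.0610 and -0.42 with 100 and 25 bp windows and -0.30 against flanks. GAGAG turned to 0.23 and 0.0261 with 100 and 25 bp windows. TATCGATA turned to -0.14 with 25 bp windows, -0.38 against flanks and -1.002 without promoter regions. Against flanks, TAATTA turned to 0.77 and TTTATG to 0.29. With 100 bp windows and promoter matching, CAGGTA turned to -0.0652, GAGAG to 0.158 and TATCGATA to -0.225.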

Other observations

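The tests on divergent promoters, mitochondrial ribosomal protein genes, the position of ACAGTG and the background draws of TAATCC were chosen after the data were seen. Those on abundantly transcribed genes, on 6-mers matched for promoters and on the first TAATCC bound were set before the data were seen. The bounds for chromosome 4 were written down before that test was run, but after the low number of regions had been seen. With 1 group of samples, no biological explanation was tested against a second condition.

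Regions at promoters lay between genes that are transcribed away from each other more often than candidates did. Of the 532 promoter regions, 457 (85.9%) had the summit upstream of the nearest TSS, against 39.8% of promoter candidates (odds ratio 9.22, 7.20 to 11.8). Between a pair of divergent TSSs at most 1000 bp apart lay 224 promoter regions (42.1%), against 4.67% of promoter candidates (odds ratio 14.8, 12.2 to 18.1, Fisher's exact test, p = 1.94e-132). Among summits upstream of the nearest TSS the shares were 42.9% and 10.4% (odds ratio 6.45, 5.22 to 7.97).

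The mitochondrial ribosomal protein genes mRpS10, mRpL41 and mRpL23 had regions among the strongest, with signals of 798, 773 and 669 at 124, 130 and 65 bp from the TSS. As a class they were not above chance, with 7 of 35 tested genes occupied against 4.98 expected (one-sided permutation test, p = 0.171). The annotation holds 73 such genes.

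The word that led the wider scan, ACAGTG, was more frequent beside the summits than at them. Its copies thinned out towards the summit, to 8.16 per 1000 regions at 0 to 19 bp, where candidates had 9.04. It was in the flanks, 51 to 150 bp from the summit, of 378 of 1470 regions (25.7%). The share rose with signal, from 15.2% (11.9 to 19.3) in the weakest bin to 22.9%, 28.3% and 36.4% (31.7 to 41.5) in the strongest, and the median log2 signal was 6.93 with the word and 6.52 without it (two-sided permutation test, p = 1.00e-05, the smallest that 100000 resamples can give). Of the 12 strongest regions, however, 2 had it. Longer forms were rarer in the background still: GCACAGTGG was in 5.85% of flanks against 0.503% (odds ratio 12.3, 8.32 to 18.1), and GTACAGTGG in 2.65% against 0.163%. Both were picked among those with the lowest p in these same regions and background, a choice that the odds ratio and its interval do not allow for. Between the flanks the sequence was poor in GC, at 36.2% within 50 bp of the summit against 44.8% at 81 to 150 bp, where candidates had 47.8% and 46.3%.

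Technical causes were tested for this position. A background with other flanks would give no excess once flank GC was matched, but the odds ratio was then 4.07 (3.52 to 4.70). Without copies in soft-masked repeats it was 4.29 (3.69 to 4.98). If summits were scattered at random around a central word, the replicates' summits would lie far from each other as well. In 367 regions with the word 51 to 150 bp from the summit, the median distance between the replicates' summits was 17.0 bp. That from the summit to the word was 86.5 bp, a ratio of 0.197 (0.156 to 0.224). The choice of regions put the word at least 51 bp away, so the ratio is in part set by it. The distance between replicates was not set in this way, and it was 51 bp or more in 55 regions. A displacement shared by both replicates stays open.

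Why strong regions lie at TSSs of genes outside the developmental lists was weighed with 3 explanations. These lists hold few of the 9245 tested genes, so most regions would lie outside them in any case. Whether strong regions avoid the listed genes was not tested. The tests were not limited to strong regions at TSSs. That of TAATCC took all 1470 regions, 938 of them outside promoters. The list test counted any assigned region, such as 1 for Act5C at 4698 bp from the TSS. These 2 tests therefore do not bear on strong TSS regions in particular, and only the last ACAGTG value below was limited to promoter regions. Unspecific signal at highly transcribed genes stays open. The abundantly transcribed and ribosomal lists together were occupied at 1.71 times the matched expectation, which meets the 1.5 set beforehand (one-sided permutation test, p = 0.0567). Meeting that bar cannot by itself show that unspecific signal is the cause. The further demand that 9 of 44 genes exceed the 95% range of random lists (2 to 9) was added after the value was seen. The 2 lists also differed, at 6.19 times the expectation for abundantly transcribed genes and 0.894 times for ribosomal protein genes. Open promoters without any sequence word are left open too: against candidates matched on GC and promoter, no 6-mer within 50 bp had an odds ratio over 3 (highest 2.10), but tests chosen later gave ACAGTG 3.02 (2.60 to 3.51) within 100 bp and 3.81 (3.30 to 4.40) in the flanks, whose lower bound is over the 3 set beforehand; in the flanks of promoter regions alone it was 3.48 (2.76 to 4.40), whose lower bound is not. By the rule set beforehand, an upper bound under 1.5, recruitment through TAATCC was excluded, as the first draw of the background gave 1.46. The 20 draws added after that was seen gave odds ratios of 1.07 to 1.26. Their upper bounds were 1.44 to 1.70, with 9 under 1.5, so recruitment through TAATCC is left open.

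Chromosome 4 was nearly empty in the ranked lists as well. Replicate 1 had 42 ranked regions there, replicate 2 39, and both together 40, which lay in 3 stretches: 6 regions from 16109 to 25343, 12 from 755029 to 761452 and 22 from 1279296 to 1318952. Of 26 windows of 50 kb, 3 held a ranked region (11.5%), against 94.7% to 98.4% on the other arms. Of these regions, 4 reached the threshold score and none is in the main list. Low GC content argues for far more, since the rates per GC bin of the other arms give 669 regions, and so does repeat content, with 1028. Loss of most of this chromosome in the authors' processing, or a difference in its copy number or chromatin, was not tested and stays open.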
